A study of Olea europaea with 24 samples.

How the data were processed

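RNA was measured by sequencing in branches of 6 olive trees sampled on 4 days, 7 May, 23 May, 6 June and 29 July, which gave 24 libraries. Days 2 to 4 fell 16, 30 and 83 days after the first. Trees 3, 9 and 11 belong to the watered arm and trees 4, 8 and 12 to the dried arm. Per the labels, irrigation was 1.2 litres per day; dried trees got 1 litre per week over 2 weeks, followed by 2 weeks without water. The sample labels do not tie these weeks to the sampling days, though the authors' comparison names, given below, use control, drought and after. Each tree was sampled on every day, so each of the 8 groups of arm and day holds 3 trees. The replicate number is the tree, so it pairs libraries between days but not between arms.

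Per the submitters' processing notes, cutadapt, RSEM, Bowtie2, DESeq2 and limma were used, with versions and the genome build not given in the sources used here. The deposited count table holds RSEM expected counts, which are not whole numbers and were rounded before testing. It has 50663 rows. Of these, 97 carry short names of carbohydrate genes given by the authors and 50566 carry gene model IDs. The gene table for the assembly O_europaea_v1 held none of those IDs, so they have no names or coordinates here. A second deposited table holds signal values that follow the rounded counts with 1 constant per library, as size-factor scaling gives; no other correction was visible in them. The authors' deposited table of comparisons gives log2 fold changes and adjusted p-values. All per-sample columns of the tables were used.

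Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, TMM scaling, filterByExpr by group, 1 mean per group, all 24 libraries). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The filter left 29107 rows, 87 of them named. Standard errors are the absolute log2 fold change over the square root of F. Levels are log2 CPM with a prior count of 2. The 13 contrasts were dried against watered on each day, each later day against 7 May within an arm, and 3 interactions (the change of the dried arm minus that of the watered arm). Where all 3 libraries of a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio of pooled rates is given with its exact 95% binomial interval. Both cover counting error only.

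Before the data were examined, 24 gene lists were fixed as name patterns, together with the contrasts, the test and the alternatives below that are not marked as added. The authors' short names match few patterns as spelled. Their families were therefore assigned to the 3 lists on starch degradation, starch synthesis and sucrose metabolism after the names, but not their test values, were seen. This gave 24, 15 and 16 tested rows. The starch synthesis list then held starchsyn, sbe and isoamylase rows other than isoamylase3, but none of the 7 agp rows. The starch degradation list held isoamylase3, but none of the 3 starchp rows, and neither the 2 aglucan rows nor gluct1. Values for these lists leave those rows out, although the patterns named ADP-glucose pyrophosphorylase and starch phosphorylase. The other 21 lists matched no row and were not analysed here. The named rows were picked by the authors, who may have used these libraries, and rows of 1 family can share reads. Counts adjusted over the list alone are therefore not independent evidence. Lists and families of 5 or more rows were tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives.

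Genes were to be named by rule: called, an absolute log2 fold change of at least 1, a mean of at least 1 log2 CPM and, outside the interactions, no overlap between groups. Up to 6 per direction were taken for contrasts between arms and 3 for others, or 2 IDs per direction where IDs have no names. The rule named starchsyn1 and hexokinase9 among named rows. Every other named row in the text was chosen after its values were seen.

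The alternatives set beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter beyond 1 count, the authors' scaled values with limma on log2(value + 1), each tree left out, the 6 libraries of a day alone, and the tree as a block. Added after seeing the data were fits without the watered 7 May library of tree 9, without the 2 libraries with the lowest counts outside 23 co-varying rows, without those rows, limma voom with quality weights, and DESeq2 with the tree as a block.

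The numbers pair the libraries because the same trees were sampled. Deviations from group means of libraries of 1 tree nevertheless correlated by -0.03 to 0.18 on average per tree. No 2 libraries held identical counts. These fits were tested on simulated counts without tree effects or outlying libraries. Changed genes were drawn from rows with an average of at least 2 log2 CPM, so recovery does not cover lower rows. Of these genes 100 were changed 4-fold and 100 were changed 16-fold in dried trees on 6 June. Between the arms on that day edgeR recovered 8 and 84 with 3 false calls, with DESeq2 size factors 8 and 85 with 3, DESeq2 27 and 92 with 25, and limma voom 8 and 74 with 1 (28138 genes). Limma on scaled values recovered 11 and 88 with 3 (29107 genes). For the interaction from 7 May to 6 June edgeR recovered 1 and 29 with 1 false call, with the tree as a block 0 and 30 with 1, and blocked DESeq2 11 and 50 with 28.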

Results

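Transcripts were counted in branches of 3 watered and 3 dried olive trees on 4 days. The series title names heat, drought and recovery. Total counts ran from 6675360 to 14122826 per library. Composition differed widely. A set of 23 abundant rows without names moved together and held 11.2% to 92.1% of a library's count. They held 72.3% ± 17.6 (SD, n = 3) in dried trees and 55.2% ± 35.4 (SD, n = 3) in watered trees on 6 June. The count left for other rows was 945233 in dried tree 4 on 6 June and 946135 in dried tree 8 on 23 May, against 9121632 in watered tree 3 on 6 June.

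**Figure D1:**
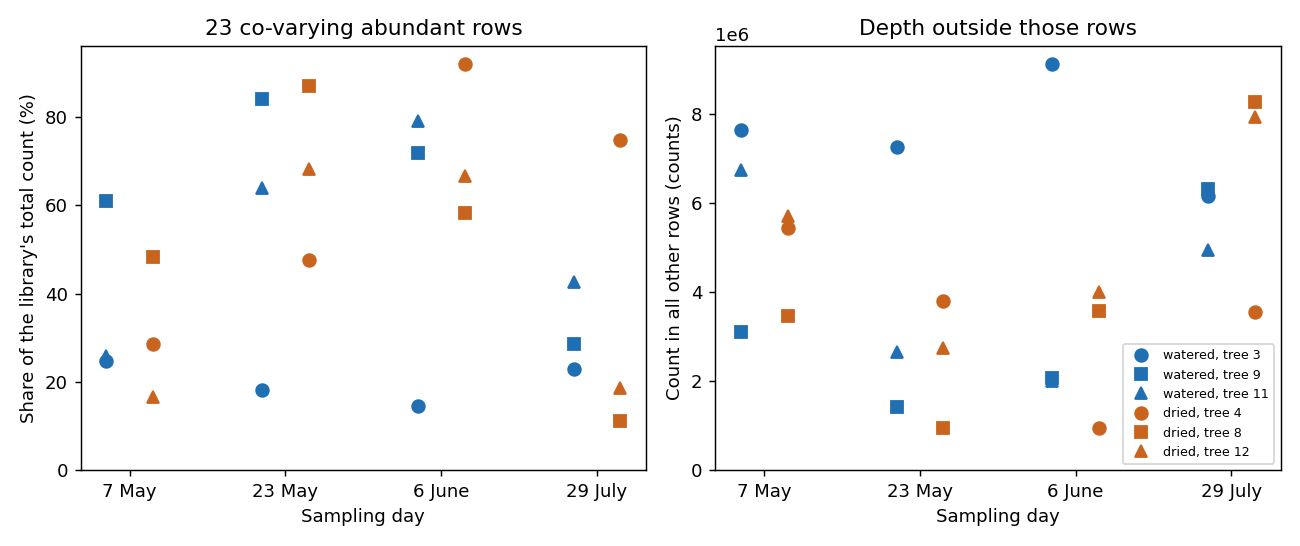
Share of each library's total count in the 23 co-varying rows (left, %) and the count in all other rows (right, counts), by sampling day, with 1 point per tree, blue for watered and orange for dried. Shares run from 11.2% to 92.1%, and the dried trees run from 11.2% to 74.8% on 29 July.

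On 7 May, the first day, no gene was called between dried and watered trees by edgeR, with 990 at an unadjusted p under 0.05 and 73 called by DESeq2. Of 24 starch degradation rows 17 had positive and 7 negative log2 fold changes, and none passed adjusted over the list alone. By camera the 5 invertase rows were lower in dried trees (median log2 fold change -2.69) and the 15 starch synthesis rows higher (0.37), each at an adjusted p of 0.0396, or 0.742 with an estimated correlation. Both rested on watered tree 9: without its library the invertase median was 3.27, in the other direction (adjusted p = 0.0101; 0.603 with an estimated correlation), and that of starch synthesis 0.04 (0.841). In the dried arm tree 12 then lay far above trees 4 and 8 for invertase2 (7.07 against -0.57 and 0.29 log2 CPM). The same held for invertase8 (6.53 against 0.16 and 1.18), but not for invertase11. Watered tree 9 stood apart. Its log2 CPM correlated at r = 0.48 to 0.61 across genes with the other 2 watered trees, which correlated at 0.88. Its bamylase2, invertase2 and sucsynthase1 levels were the highest of the 6 libraries of the day in the plot of carbohydrate genes.

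On 6 June named rows for starch and sucrose enzymes differed between the arms. Watered tree 3 stood apart on this day, at r = 0.71 to 0.73 with watered trees 9 and 11, which correlated at 0.87. Its agp2 level was 8.21 log2 CPM against 4.91 and 4.63 in those trees. Starchsyn1, a starch synthase that builds starch chains, was lower in dried trees, by 80.1-fold in pooled counts (95% interval 22 to 663; 2 counts against 390). Its log2 fold change was -5.90 ± 1.12 (SE, n = 3 trees per arm, edgeR adjusted p = 0.0472), and it was the only named row called over all genes. The row hexokinase9, a hexokinase that phosphorylates glucose, had 0 counts in the 3 dried trees against 179, at least 24.5-fold lower, with an edgeR adjusted p of 0.0560. Invertases, which split sucrose, stood higher in dried trees. Invertase2 was at 7.45 ± 1.27 log2 CPM against 0.54 ± 0.50, and invertase8 at 6.54 ± 1.12 against -0.33 ± 1.92 (SD, n = 3).

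By list, 5 of 16 sucrose metabolism rows rose and 2 fell adjusted over the list alone, with none called over all genes. Those that rose were invertase1, invertase2, invertase8, invertase11 and sucsynthase1, and those that fell were sucsynthase10 (-3.19 ± 1.02) and sucsynthase11 (-2.34 ± 0.66, log2 fold change ± SE). The 5 invertase rows were tested as a set, all with positive folds (median 6.73), at a camera adjusted p of 0.000462; the adjusted p was 0.506 with an estimated correlation. In starch synthesis 2 of 15 rows fell adjusted over the list alone, starchsyn1 and starchsyn8 (-3.32 ± 0.79), and 13 of 15 folds were negative. The 7 agp rows, outside that list, had 1 positive and 6 negative folds (median -2.63, camera adjusted p = 0.2). In starch degradation 1 of 24 rows fell adjusted over the list alone, mex1, a maltose exporter by its name, at 3 counts against 160. Of the 13 beta-amylases, which release maltose from starch, bamylase6 fell (-1.14 ± 0.37) adjusted over the 87 named rows alone, and not over the list alone or all genes. The others did not pass, bamylase2 (1.97 ± 1.11) and bamylase10 (1.70 ± 0.97) among them. The authors chose these rows, so counts over them alone are not independent evidence. Over the 87 named rows alone, 5 were higher and 14 lower, agp2, agp3, agp5 and gpt2 among the lower.

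**Figure D2:**
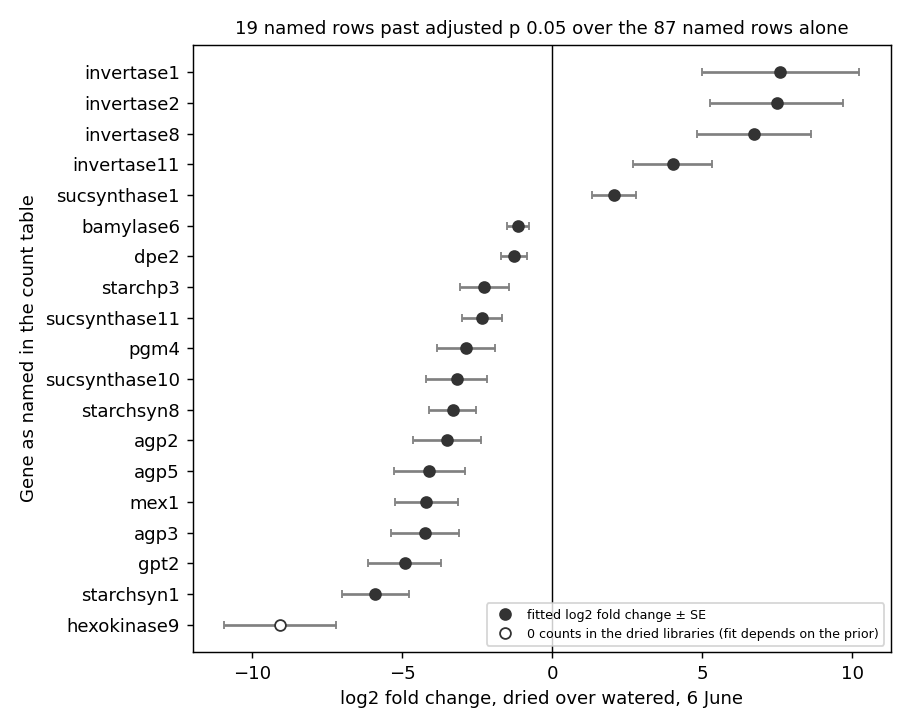
Log2 fold change of dried over watered trees on 6 June with its SE (x axis) for the 19 named rows that passed adjusted p 0.05 over the 87 named rows alone (y axis), with an open circle where the dried libraries held 0 counts. The 5 rows to the right of 0 are 4 invertases and sucsynthase1, and 14 lie to the left.

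Over all 29107 genes edgeR called 30 on 6 June, 6 higher and 24 lower in dried trees, with adjusted p from 0.0472 and 7059 at an unadjusted p under 0.05. Oeu044065.1 (9.34 ± 1.64) and Oeu026673.1 (5.10 ± 0.99) had the largest positive log2 fold changes, and Oeu036692.1 and Oeu001292.1 were at least 228- and 73.9-fold lower, with 0 counts in dried trees. No gene was called without tree 4, 8, 11 or 12 or without the 23 rows, while 81 were called without tree 3, 2236 without tree 9, and 3405 without only the watered 7 May library of tree 9, which is not part of this contrast. That library can act on it only through the estimate of spread, the filter and the scaling, which all 24 libraries share. DESeq2 called 4135, with 2699 lower. With the libraries of that day alone more genes were higher than lower, so the balance of directions depended on the processing.

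On 23 May no gene was called between the arms by edgeR (3246 at an unadjusted p under 0.05; DESeq2 called 359). Watered tree 9 stood apart on this day too, at r = 0.48 to 0.64 with trees 3 and 11, which correlated at 0.80. Watered tree 3 correlated more highly with dried tree 4 of the day (0.91) than with its own group (0.48 to 0.80). Both watered libraries enter all watered values of 23 May, and no fit left either out alone. By list, 2 of 15 starch synthesis rows were lower in dried trees adjusted over the list alone, starchsyn1 (-2.99 ± 0.85) and starchsyn8 (-3.05 ± 0.77), and none of the starch degradation or sucrose metabolism rows passed so. By family, the same 2 of 10 starchsyn rows and 1 of 7 agp rows were lower adjusted over the family alone. None of the 87 named rows passed over those alone. Bamylase10, which did not pass, stood at 11.16 ± 0.47 log2 CPM in dried and 9.05 ± 1.33 in watered trees, and bamylase2, which did not pass either, at 10.98 ± 0.20 and 9.20 ± 1.34 (SD, n = 3). Agp2 stood at 0.58 ± 1.25 and 3.33 ± 0.74. Among the watered trees, tree 3 lay nearest the dried levels of bamylase10 and bamylase2. It had 10.55 and 10.67 log2 CPM, against 8.01 and 8.04 in tree 9 and 8.59 and 8.89 in tree 11. On 29 July, with 41 genes at an unadjusted p under 0.05 in edgeR and 16 called by DESeq2, edgeR again called none. Starchsyn1 was then at 3.52 ± 0.28 in dried and 3.45 ± 0.41 in watered trees, and bamylase10 at 5.74 ± 0.31 and 5.63 ± 0.21 (SD, n = 3).

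**Figure D3:**
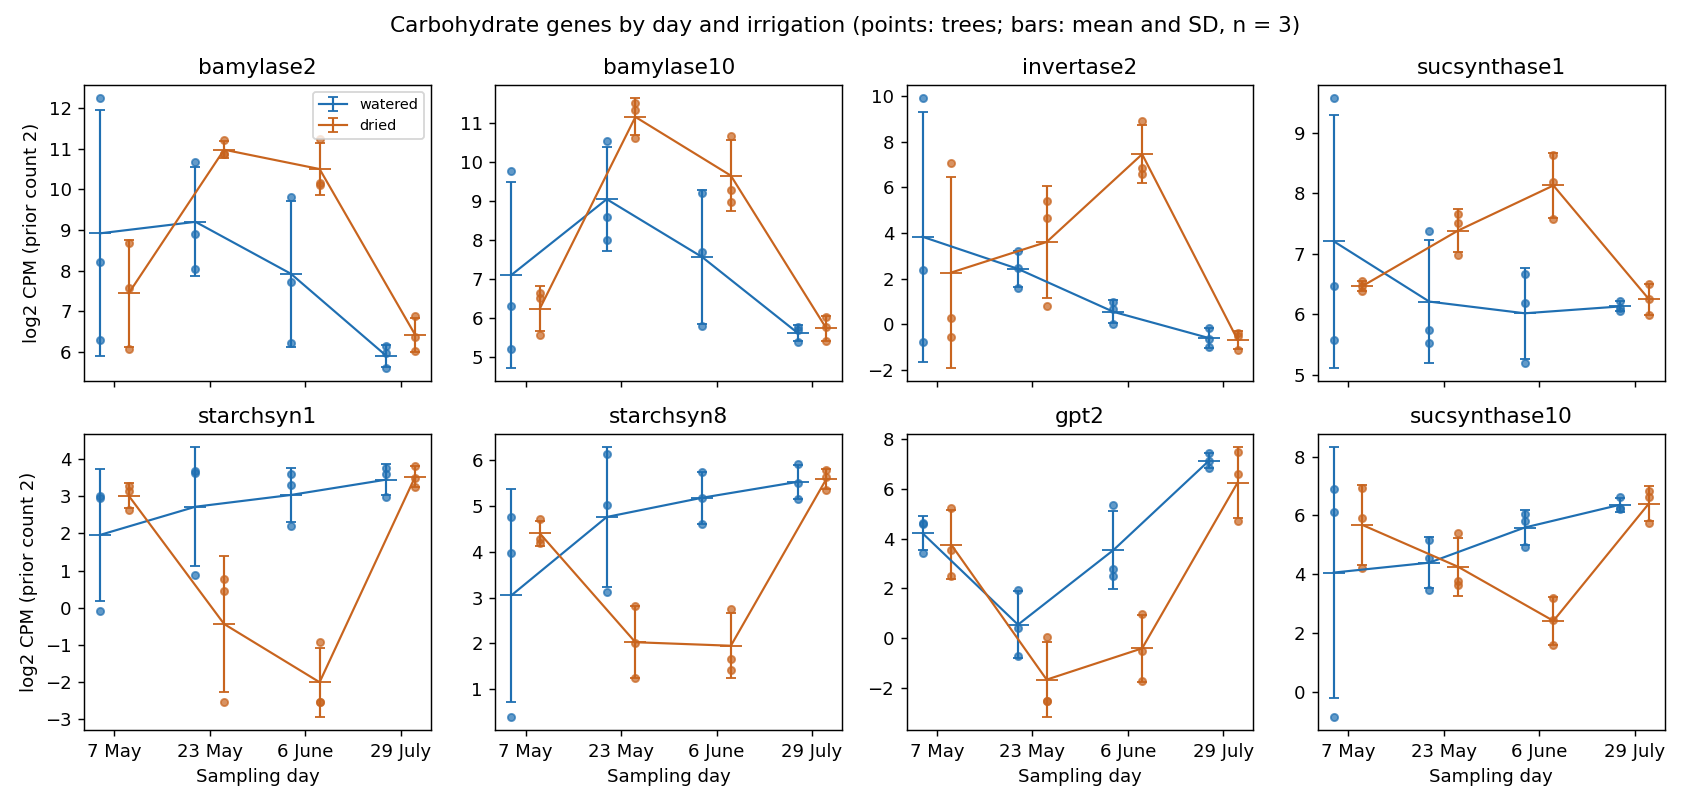
Log2 CPM (y axis) of 8 named genes by sampling day (x axis), with 1 point per tree and bars for the mean and SD (n = 3), blue for watered and orange for dried. In dried trees bamylase10 averages 11.16 on 23 May and 5.74 on 29 July, and starchsyn1 averages -2.00 on 6 June and 3.52 on 29 July.

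Within the dried arm, the change from 7 May holds season and irrigation together. On 6 June starchsyn1 fell to 2 pooled counts from 312, 62.7-fold (95% interval 17.2 to 520), and hexokinase9 to 0 from 141, at least 18.9-fold, each at an edgeR adjusted p of 0.0470. Adjusted over the 87 named rows alone, 16 fell, with 5 of 7 agp rows lower adjusted over that family alone, and bamylase10 rose by 3.53 ± 1.04. With the tree as a block 18 of the 87 fell and 1 rose. By camera the agp rows were lower and the invertase rows higher (adjusted p = 0.0272 and 0.024; 0.702 each with an estimated correlation). Starch synthesis and all 87 named rows as a set also passed with the tree as a block, both lower, from an adjusted p of 0.051 to 0.0349 each (0.751 with an estimated correlation, unblocked). EdgeR called 316 genes, 61 higher and 255 lower, with adjusted p from 0.047. The largest positive fold among IDs was that of Oeu052284.1, at least 2296-fold with 0 counts on 7 May, followed by Oeu044479.1 (9.23 ± 2.09), and Oeu003595.1 was at least 106-fold lower, with a larger bound still for Oeu018706.1. With the tree as a block edgeR called 0 (6927 at an unadjusted p under 0.05; DESeq2 with the block 4756). Leaving out tree 4, 8, 11 or 12 also gave 0, and leaving out tree 3 or 9 gave 1653 or 3748.

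On 23 May bamylase10 rose in dried trees by 4.88 ± 1.11 on the log2 scale, and agp2 (-6.22 ± 1.31) and gpt2 (-5.75 ± 1.27) fell, adjusted over the 87 named rows alone and not over all genes. Of those 87, 5 passed, and 3 with the tree as a block. The 7 agp rows were lower as a family (camera adjusted p = 0.0432; adjusted p = 0.941 with an estimated correlation). EdgeR called 42 genes, 15 higher and 27 lower, led by Oeu023323.1 (9.32 ± 1.82), Oeu044065.1 (8.43 ± 1.56) and Oeu057521.1 (-8.12 ± 1.57). Oeu023118.1 was 111-fold lower in pooled counts (95% interval 19.7 to 4398; 1 count against 266). With the tree as a block 6 were called. Leaving out tree 4, 8 or 12 gave 0, tree 11 gave 1, and tree 3 or 9 gave 945 or 1392. On 29 July edgeR called none against 7 May, with 906 at an unadjusted p under 0.05, and DESeq2 called 48.

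Within the watered arm, no named row was called over all genes on any day. On 23 May the 5 gpt rows, glucose-phosphate transporters by their name, were all lower than on 7 May (median log2 fold change -1.19, camera adjusted p = 0.0036; 0.0239 with an estimated correlation, 0.00475 with the tree as a block, fry 6.42e-05). Of the 15 camera calls over all contrasts this was the 1 that passed with an estimated correlation. That correlation was negative for the gpt rows (-0.119), against 0.654 for the invertase rows, so it was a weaker check for gpt. Without the watered 7 May library of tree 9, 4 of 5 gpt rows were lower (camera adjusted p = 0.0378, and 0.105 with an estimated correlation). The others in this arm were invertases lower on 6 June (adjusted p = 0.00239; 0.38 with an estimated correlation) and 29 July (0.0026). On 29 July starch synthesis (0.00742), agp (0.0333) and starchsyn rows (0.0474) were higher, all 4 at 0.692 with an estimated correlation. None of these 5 passed without that library: the invertase medians went from -6.87 to -0.08 and from -6.36 to -0.64, with adjusted p of 0.821 and 0.79, and the other 3 had adjusted p of 0.167, 0.167 and 0.208. On 29 July invertase1, invertase2 and bamylase2 (-4.86 ± 1.26) were lower than on 7 May adjusted over the 87 named rows alone, and 0 rows passed with the tree as a block. Invertase1 and invertase2 overlapped between the days, with watered tree 9 the highest library on 7 May. Without that library the log2 fold changes of invertase1, invertase2 and bamylase2 on 29 July were -0.64, -2.38 and -1.64. On 23 May edgeR called 6 genes, 3 higher and 3 lower, among them Oeu033900.1 (4.93 ± 0.82), Oeu056211.1 (4.83 ± 0.84), Oeu049229.1 (-4.76 ± 0.77) and Oeu024088.1 (-4.62 ± 0.70). With the tree as a block edgeR called 0 (2888 at an unadjusted p under 0.05; DESeq2 with the block 901), and leaving out any 1 of the 6 trees also gave 0. EdgeR called none on 6 June (2623 at an unadjusted p under 0.05; DESeq2 494) or on 29 July (2390; DESeq2 729).

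The interactions ask whether the arms moved apart. From 7 May to 6 June starchsyn1 went from 3.02 ± 0.34 to -2.00 ± 0.93 log2 CPM in dried trees and from 1.96 ± 1.78 to 3.04 ± 0.73 in watered trees (SD, n = 3). Its log2 interaction was -6.41 ± 1.35 (SE, edgeR adjusted p = 0.0464), and hexokinase9 was also called (adjusted p = 0.0483). Adjusted over the 87 named rows alone, 7 had positive and 6 negative interactions, invertase11 (6.69 ± 1.80), sucsynthase1 (3.82 ± 1.04) and bamylase2 (4.94 ± 1.60) among the positive. With the tree as a block 4 passed, 1 positive and 3 negative. By camera the invertase rows were positive and the starch synthesis rows negative (adjusted p = 0.000314 and 0.0469; 0.462 and 0.712 with an estimated correlation). Without the watered 7 May library of tree 9 the invertase median went from 8.72 to 3.42, with 4 of 5 rows positive (adjusted p = 0.00138; 0.318 with an estimated correlation), and starch synthesis did not pass (0.0845). Single interactions without it were 3.12 for invertase11, 1.68 for sucsynthase1 and 1.73 for bamylase2. From 6 June to 29 July the invertase rows were negative (0.000208; 0.419). EdgeR called 310 genes, 255 of them positive, with adjusted p from 0.045. The IDs with the largest values were Oeu016606.1 (17.81 ± 4.24, and 6.37 without that library) and Oeu049712.1 (17.66 ± 3.48, and 9.14), and the lowest included Oeu036692.1 and Oeu001292.1, whose dried trees held 0 counts on 6 June. EdgeR called 0 without the watered 7 May library of tree 9, 0 with the tree as a block (5327 at an unadjusted p under 0.05; DESeq2 with the block 2695), and 0 without any 1 of trees 4, 8, 9, 11 and 12. Without tree 3 it called 1495. From 7 May to 23 May none was called (2752 at an unadjusted p under 0.05; DESeq2 261), and from 6 June to 29 July none (3543; DESeq2 267).

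The authors' deposited table lists 112 genes with an adjusted p under 0.05 for its first control and drought comparison. It lists 7 for a comparison named after 3 and control 3. For the second control and drought comparison it lists 2554. With the sign turned to dried minus watered, fold changes of the second in the authors' deposited table correlated across genes at r = 0.98 with the tree-blocked interaction on 6 June and at 0.96 with the unblocked one. With that sign 1354 of the 2554 genes were positive and 1200 negative. This balance was nearer even than the 255 positive of 310 that edgeR called without the block. Tool, design and number of calls differ between these, and edgeR with the tree as a block called 0. In the authors' deposited table starchsyn1 has 6.33 (log2, sign not turned) for that comparison, with an adjusted p of 0.00218, where the tree-blocked interaction was -6.33.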

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

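The tests of a direct swap, of a wrong label and of scaling, and the fits without a single library, without 2 libraries and without the 23 rows, were chosen after the results were seen. The interaction from 7 May to 6 June was picked out because a test of the difference itself, without the tree as a block, found that the arms changed differently. EdgeR called 310 genes, among them starchsyn1 with a log2 interaction of -6.41 and hexokinase9 with an adjusted p of 0.0483. Of the 10 splits of the trees 1, the real one, called as many, and the highest other, with trees 3, 4 and 8 against the rest, called 108. With 10 splits no share under 0.05 can be reached. Without the watered 7 May library of tree 9 edgeR called 0, with starchsyn1 at -5.98 and an adjusted p of 0.182. With the tree as a block edgeR also called 0, with starchsyn1 and hexokinase9 each at an adjusted p of 0.176.

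The watered 7 May library of tree 9 stood apart from the other 2 of its group. With each library thinned to 935684 counts outside the 23 rows, trees 3 and 11 correlated across genes at r = 0.70, which was 0.18 above the highest value of tree 9 with them (SD 0.0019 over 10 draws), so shallow depth is not the whole cause. A direct swap with another library stays open. It needs a library that is closer to trees 3 and 11 than to its own group and about as close to them as they are to each other (0.88), and whose group takes tree 9 in return. Within 0.05, 1 library met this: watered tree 11 on 23 May had 0.84 with trees 3 and 11 against 0.72 with its group, and tree 9 had 0.56 with the other 2 of that group against 0.48 between them. Without that margin 0 met it. The 0.48 lies between trees 3 and 9 of 23 May, and tree 9 stood apart on that day too (0.48 to 0.64). That part is therefore easily met, so the test cannot decide on a swap. A single wrong label and a difference of that tree on that day cannot be told apart: its highest mean correlation, 0.76 with the dried trees of 6 June, lay between the 0.75 and 0.80 of those trees with each other, against 0.55 with its own group.

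Carbohydrate rows differed between the arms on 6 June. Without the 2 libraries of low depth the 19 rows past the threshold over the named rows alone had a median absolute log2 fold change 1.01 times that with them. Of these 2 libraries only that of dried tree 4 is in this contrast, and the 19 rows were chosen with it included. These 2 libraries are therefore not the whole cause. Whether the lower depth of the dried arm as a whole plays a part was not tested. Scaling moved by the 23 rows, with 1 factor per library, moves every gene alike, whereas 5 of the 19 lay above and 14 below the median of all genes, so it is not the whole cause either. Their median absolute log2 fold change was 4.01 with the 23 rows and 3.99 without. The call of starchsyn1 did end: its log2 fold change went from -5.90 ± 1.12 to -5.78 ± 1.10 (SE) without the 23 rows and -5.77 ± 1.19 without the 2 libraries, and its edgeR adjusted p from 0.0472 to 0.0541 and 0.0624, which lie just past 0.05 and within 0.00471 to 0.235 over its alternatives with edgeR. Irrigation, differences between the trees and reads shared within a family stay open and were not tested.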

How the results depend on the processing

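The numbers of calls depended on the processing. Of the genes named by the rule and the named rows past the threshold over the 87 alone, each followed in the contrast where it passed, 0 reversed in any alternative. This does not cover rows that passed over a smaller list alone, or not at all. In watered trees on 23 May 3 of 5 invertases were lower adjusted over the family alone, and all 5 turned positive without the watered 7 May library of tree 9. On 6 June 23 named genes and IDs between the arms gave 345 values under alternatives, of which 233 kept their side of the threshold, 30 fell behind it and 82 came past it. Only starchsyn1 and the IDs were called over all genes to begin with, so all 30 losses were theirs. The other rows kept their side only by staying uncalled. The fits without a library, without the 23 rows, with voom and with the blocked DESeq2 were chosen after seeing the data. The cause was not tested, except that fits without libraries or rows differ by those alone. The lowest edgeR adjusted p was 0.0472 between the arms on 6 June and 0.00812 in dried trees on 23 May. It was 0.047 in dried trees on 6 June and 0.045 for the interaction to 6 June, so all calls there lie near 0.05. Depth limits low genes most in dried tree 4 on 6 June and dried tree 8 on 23 May, with 945233 and 946135 counts outside the 23 rows. With DESeq2 the arms differed in 73, 359, 4135 and 16 genes on 7 May, 23 May, 6 June and 29 July. Against 7 May it called 1825, 494 and 729 in watered trees on the 3 later days and 2706, 4477 and 48 in dried trees. For the interactions it called 261, 2864 and 267. With its size factors in edgeR the counts were 49 between the arms on 6 June, 26 and 78 for watered and dried trees on 23 May, and 573 for the interaction to 6 June. With no filter they were 546, 10, 486 and 751 in that order, and 701 for dried trees on 6 June. With limma on the authors' scaled values they were 1032, 37, 539 and 0 in that order, and 858 for dried trees on 6 June. With the 6 libraries of 6 June alone, 1102 genes differed between the arms, 642 higher and 460 lower in dried trees, with a median log2 fold change of 0 over all genes. With the tree as a replicate block, since the same trees pair the days, edgeR called 0 for watered trees on 23 May, 6 for dried trees on 23 May, 0 for dried trees on 6 June and 0 for the interaction to 6 June. For the other day and interaction contrasts 0 were called over all genes with and without the block. Over the 87 named rows alone the block changed the calls from 3 to 0 in watered trees on 29 July, 5 to 3 and 17 to 19 in dried trees on 23 May and 6 June, and 13 to 4 for the interaction to 6 June. Of 108 list tests in those contrasts 12 passed without the block and 15 with it, 12 of them shared. The added 3 were all named rows in watered trees on 29 July (adjusted p 0.0606 to 0.0355; 0.692 with an estimated correlation, unblocked), and starch synthesis and all named rows in dried trees on 6 June (0.751 each, likewise). With DESeq2 and the tree as a replicate block, watered trees gave 901, 223 and 437, dried trees 2928, 4756 and 42, and the interactions 168, 2695 and 241. Without the watered 7 May library of tree 9 the arms differed in 3405 genes on 6 June. Watered trees on 23 May then gave 2, dried trees 1467 and 3461 on 23 May and 6 June, and the interaction to 6 June 0. Without the 2 libraries of low depth, watered and dried trees on 23 May gave 0 and 0, dried trees on 6 June 8, and the interaction to 6 June 0. Without the 23 rows the arms on 6 June gave 0, watered and dried trees on 23 May 0 and 4, and dried trees on 6 June 0, while the interaction to 6 June gave 459, against 310 with them. With voom and quality weights the arms gave 571, 1594 and 2 on the 3 later days. Watered trees gave 40 and 97 on 23 May and 29 July, dried trees 4280, 3638 and 717, and the interactions to 6 June and from 6 June 675 and 603. Leaving out 1 tree at a time gave 0 to 21 and 0 to 2236 between the arms on 23 May and 6 June, and 0 throughout for watered trees on 23 May. It gave 0 to 1392 and 0 to 3748 for dried trees on 23 May and 6 June, and 0 to 649, 0 to 1495 and 0 to 2 for the interactions. Of 156 tests of lists and families, 15 passed with the preset correlation, 1 with an estimated correlation and 5 with fry. Without the watered 7 May library of tree 9, chosen after seeing the data, 11 passed, 8 of them shared, and 7 of those with the same sign of the median: the invertase median between the arms on 7 May turned from -2.69 to 3.27. It also turned, without a camera call, from -4.50 to 2.02 in watered trees on 23 May and from 3.99 to -2.16 for the interaction to 23 May. The median log2 fold change of all genes between the arms on 6 June was -0.25 with all libraries and rows, and -0.12 without the 23 rows. For the interaction to 6 June it was -0.40 and -0.27.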

Other observations

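The test of the ratio of the 23 rows was chosen after their ratio over all libraries had been seen; the counts over other splits were set before. The rows named here were chosen after their values were seen, and no test was made over all 4 days together. In dried trees gpt2, a glucose-phosphate transporter by its name, averaged 3.76 ± 1.39 log2 CPM on 7 May, -1.68 ± 1.49 on 23 May, -0.41 ± 1.35 on 6 June and 6.26 ± 1.42 on 29 July (SD, n = 3). In watered trees it averaged 4.22 ± 0.68, 0.54 ± 1.35, 3.54 ± 1.58 and 7.14 ± 0.30 on those days. Starchsyn4, a starch synthase by its name, averaged 8.21 ± 1.10, 6.34 ± 0.77, 6.66 ± 1.14 and 9.70 ± 0.36 in dried trees, and 8.15 ± 2.61, 6.60 ± 0.10, 8.21 ± 1.19 and 9.86 ± 0.03 in watered trees.

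The 23 abundant rows moved in a nearly constant ratio. With rows chosen in the watered libraries alone, 22 rows besides the largest had a median SD of 0.15 for their log2 ratio to it in the dried libraries. For 28 other abundant rows it was 2.36, which gives a ratio of 0.0646. A common source of these rows is a candidate explanation. The rows have no names here, so what that source is was not tested, and no biological explanation was tested.

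Other splits of the same libraries were counted for each contrast, and with 10 splits no share under 0.05 can be reached. Between the arms the real splits called 0, 0, 30 and 0 genes on the 4 days and the highest others 135, 2, 0 and 0. As many as the real split were called by 10, 10, 1 and 10 splits. For watered trees against 7 May the real counts were 6, 0 and 0 on the 3 later days and the highest others 532, 204 and 0, with 4, 10 and 10 splits as large. For dried trees the real counts were 42, 316 and 0 and the highest others 0, 2 and 0, with 1, 1 and 10 splits as large. The splits between days dealt libraries across trees and used the fit without the block, so they ignore that trees pair the days. With the block the real counts for dried trees were 6 on 23 May and 0 on 6 June. For the interactions to 23 May, to 6 June and from 6 June the real counts were 0, 310 and 0 and the highest others 1451, 108 and 0, with 10, 1 and 10 splits as large. Splits that called 135, 204 and 1451 genes where the real split called 0, and 532 where it called 6, may reflect a structure of the samples that the groups do not describe. The 532 came from exchanging the 7 May and 23 May libraries of watered tree 9. Exchanging its 7 May library with that of tree 11 on 23 May gave 526. By correlation the first exchange fell short of the margin for a swap: tree 9 of 23 May had 0.58 with trees 3 and 11 of 7 May.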
